A study of Mus musculus with 6 samples.

How the data were processed

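Gene expression was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays, which carry short oligonucleotide probe sets for mouse transcripts. The RNA came from 1 mouse hepatocellular carcinoma (HCC) cell line grown in DMEM with fetal bovine serum. The cells had received a pLKO lentiviral vector with a short hairpin RNA against GFP (shGFP), a sequence that is not a mouse gene, or against KLF6 (shKLF6), a zinc finger transcription factor. Each vector was used in 3 numbered infections, so that each group held 3 arrays. Total RNA was isolated with Trizol and labelled with biotin by the 3' IVT Express kit, per the labels' protocols.

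The deposited values were log2 expression values made by the authors with RMA, which corrects background, normalizes quantiles across arrays and summarizes the probes of a probe set. RMA and the affy package are named in the submitters' processing notes, and their versions are not given in the sources used here. RMA compresses differences of dim probe sets, and quantile normalization forces a near-equal distribution on all arrays, so a change in total mRNA per cell cannot be seen. The medians of the 6 arrays lay between 5.18 and 5.24 log2 units. The 45101 probe sets comprised 64 control probe sets, 34945 with 1 gene symbol, 932 with several and 9160 for which no gene is listed here. Of the probe sets with 1 gene, 34741 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols needed updating. No genome build was named for these values, so no coordinates are given.

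One probe set per gene was kept, the one with the highest mean over the 6 arrays among those naming exactly 1 gene, which gave 18194 genes. Of these, 9009 had over 1 probe set. No filter was set on dim probe sets. The number of arrays limits the precision. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were compared with limma's camera at its preset inter-gene correlation of 0.01, with the correlation estimated per list, and with fry. With an estimated correlation camera's p rests on the residual degrees of freedom, the number of arrays less the number of fitted terms. With 6 arrays these are few, and fewer still with the block or a covariate. Such a p can hardly be small, so a high one does not show that a list did not move. The 43 lists covered the KLF and SP family, reported KLF6 targets, pathways of growth, stress, adhesion, signalling and metabolism, markers of liver and other cell types, and the ribosomal and small RNA machinery. Two-sided exact permutation tests were used for single values, and 3 arrays against 3 cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9.

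The groups, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule took Klf6 and every KLF or SP member past the threshold. It then took the 12 genes in each direction with the largest change among those past it or, where fewer passed, those with the smallest unadjusted p and no overlap between groups, leaving out clone names. It also took leading members of each list, and where none passed, the 1 with the smallest unadjusted p. Other list members are named because they passed when adjusted over the list alone with the infection number as a block, or as examples of a list, and were chosen after their values were seen.

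The design had no pairing as its first choice, and a fit with the infection number as a replicate block was listed as the alternative. Whether the numbers pair the arrays was decided from the correlation of deviations from the group means between arrays of the same number. It was 0.28, 0.668 and 0.686 for the 3 pairs, all over the set minimum of 0.1, against at most 0.187 between different numbers, and each of the 6 arrays correlated best with its own number. The numbers, which come from the sample titles, were therefore taken to pair the arrays, and blocked values are given where they change a call. These correlations compare only arrays of different groups. Deviations within a group sum to 0, which pushes the correlations of different numbers down, and no chance share was computed. The pairing is weak for infection 1. Over all values shGFP 1 correlated with shKLF6 1 at 0.985, below shKLF6 2 (0.988) and shGFP 3 (0.992). The blocked p-values rest on this pairing. The p-values measure the spread between infections of 1 cell line, not between cell lines or hairpins.

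The test was checked on simulated data for shKLF6 against shGFP over 18194 genes, with noise drawn from the fitted spread. Of 50 genes changed 2-fold, 28% were recovered without the block and 50% with it. At 4-fold these shares were 78% and 90%, and at 1.41-fold they were 2% in both. Of 3 lists shifted by 0.3 log2, 3 were called, and of 23 lists without shifted genes, 0 were called. The simulated genes were independent, which real lists are not. Every member of a shifted list moved by the full 0.3 log2, more than the median of any list called below for the hairpins. Recovery of such smaller and mixed shifts was not tested. Genes changed 1.41-, 2-, 4- and 16-fold, 50 of each, were run together, which eases the adjusted threshold for the smaller changes. Without the block, differences between infections entered only as independent noise. The shares may therefore be too high for these arrays.

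Alternatives covered quantile normalization once more, median centring, the moderation of the spread, array weights, a filter on dim genes, the choice of probe set, the block, thresholds, set tests and leaving out each array. The mean level of the poly-A labelling controls as a covariate, leaving out shGFP 1 and 2, and the block with an estimated inter-gene correlation or with the poly-A covariate were chosen after seeing the data, as were the estimated correlation without each array or with the covariate and the paired comparison of array quality. So was the bound of 1.5 times for naming genes whose difference shrank over the mean of their probe sets, and the comparison of levels with the arrays' lower quartile. RMA values carry no detection call, so a low level cannot be told from background.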

Results

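The 6 arrays compared HCC cells with a KLF6 hairpin against HCC cells with a GFP hairpin, to find which genes change when KLF6 is knocked down. Each group held 3 arrays, 1 for each numbered infection of the same cell line. Values are RMA log2 levels, and errors are standard deviations over the 3 arrays of a group unless stated otherwise.

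Klf6 mRNA was lower in shKLF6 than in shGFP cells in each of the 3 infections. On its brightest probe set the level was 11.06 ± 0.71 in shGFP and 10.36 ± 0.85 in shKLF6 cells (SD, n = 3 each), a difference of -0.70 log2 or 1.62-fold. The differences within infections 1, 2 and 3 were -0.50, -0.63 and -0.96, and 61.7% of the shGFP level remained on average. The other probe sets of Klf6 agreed in direction in all 3 infections, with mean differences from -0.55 to -0.82 log2 over all 5. The level of Klf6 also varied between infections within a group. It was 10.81, 11.85 and 10.50 in the shGFP arrays of infections 1, 2 and 3, a range of 1.35 log2 or 2.56-fold, and shKLF6 cells of infection 2 (11.23) held more Klf6 mRNA than shGFP cells of infections 1 and 3.

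Without the infection number the difference in Klf6 did not exceed the spread between arrays (limma p = 0.228, adjusted p = 0.993; two-sided exact permutation p = 0.4, where 0.1 is the smallest possible). With the replicate block the unadjusted limma p was 0.00254 (limma adjusted p = 0.281 over all genes), and an exact sign-flip permutation test of the 3 paired differences gave p = 0.25, the smallest it can give. The difference was -0.30 without shGFP 2, -0.29 without shKLF6 3, -1.13 without shKLF6 2, -0.14 without shGFP 1 and 2, -0.18 with the level of the poly-A labelling controls as a covariate, and -0.02 with array weights. These fits were not paired, so the differences in Klf6 between infections enter them. With the block and the poly-A covariate the difference was -0.98 (limma, unadjusted p = 0.0124, adjusted p = 0.851). Within infection 3, where the poly-A controls differed by -0.10, it was -0.96.

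**Figure D1:**
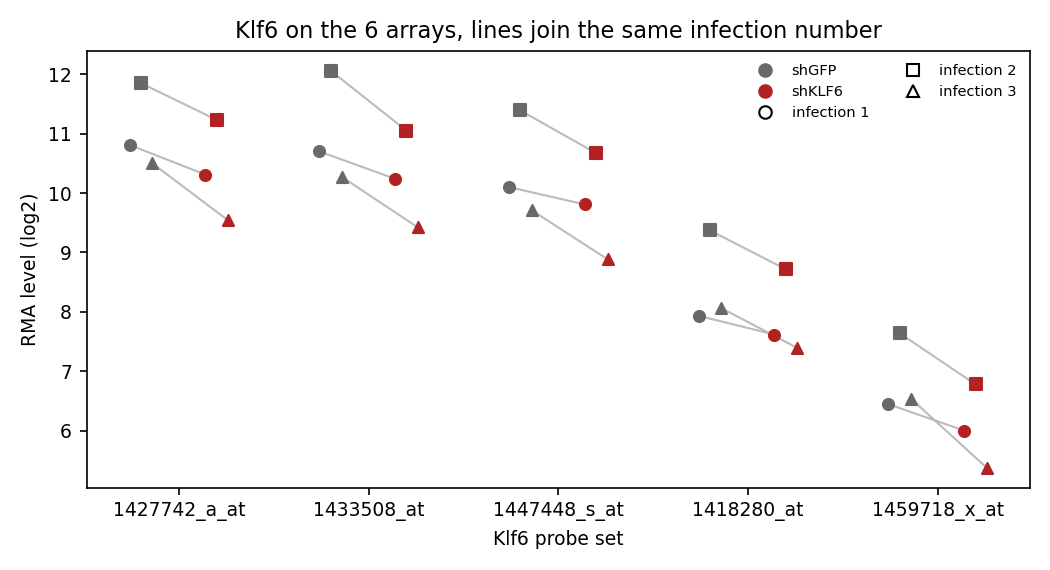
RMA level (log2, vertical axis) of the 5 Klf6 probe sets on each array, with shGFP in grey and shKLF6 in red, marker shape giving the infection number and lines joining the arrays of the same number. Every line descends from shGFP to shKLF6, by 0.50 to 0.96 log2 on the brightest probe set, while infection 2 lies above the others in both groups.

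The genes that differed most evenly between the groups included an extracellular protease, a MYC family factor and a progenitor marker at higher levels, and a desmosomal protein and an enzyme of nucleotide sugar synthesis at lower levels. Plau, which encodes the urokinase-type plasminogen activator, was 5.66 ± 0.32 in shGFP and 7.43 ± 0.44 in shKLF6 cells (SD, n = 3 each), 3.39-fold higher. Mycl, a MYC family transcription factor, was 2.28-fold higher (6.07 ± 0.24 against 7.25 ± 0.18, or 0.49 log2 over the mean of its 3 probe sets in place of 1.19), and Prom1, which encodes the progenitor marker CD133, 2.09-fold higher (8.15 ± 0.26 against 9.22 ± 0.30). Uap1, an enzyme of UDP-N-acetylglucosamine synthesis, was 2.63-fold lower (9.48 ± 0.07 against 8.08 ± 0.39). Dsp, which encodes the desmosome protein desmoplakin, was 1.63-fold lower (11.5 ± 0.12 against 10.8 ± 0.11).

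None of these genes passed when all genes were tested. Limma called 0 of 18194 genes at an adjusted p under 0.05 (lowest adjusted p = 0.993), and 864 genes had an unadjusted p under 0.05, 392 higher and 472 lower, where chance gives 909.7. With the replicate block limma again called 0 genes (lowest adjusted p = 0.159, for Plau), and 1902 genes had an unadjusted p under 0.05, 801 higher and 1101 lower, 789 of them among the 864. The groups did not overlap for 1857 genes or 10.2%, against 10% by chance. An absolute difference of at least 1 log2 was seen for 177 genes, of which 131 had the same sign in all 3 infections. The 864 became 449 without shGFP 1, 532 without shGFP 3, 467 without shKLF6 1, 1868 without shKLF6 3 and 491 without shGFP 1 and 2.

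The other genes with the smallest unadjusted p among those with higher levels were Flrt2 (1.07 log2), the basic helix-loop-helix factor Tcf4 (1.07), the adhesion receptor gene Adgrf5 (0.98), Lrch2 (0.89), the tetraspanin gene Tspan2 (0.82), the aggrecanase gene Adamts4 (0.82), the stress kinase gene Map3k20 (0.72), the immune checkpoint gene Cd276 (0.70) and the cytoskeletal gene Gas2 (0.58). Those with lower levels were the endolysosomal channel gene Tpcn1 (-1.09 log2), the transcription factor gene Nfic (-1.08), Megf9 (2-fold lower), the protease inhibitor gene Serpinb8 (-0.89), the torsin gene Tor1b (-0.86), Ccpg1os (-0.84), the glycosyltransferase gene Glt8d1 (-0.81), Ahnak2 (-0.66), the Fanconi anemia pathway gene Faap20 (-0.65) and the microtubule-binding gene Map4 (-0.62). All 24 genes, which were chosen for even differences, had the same sign in 3 of 3 infections, as had 34.1% of all genes. None passed in limma (adjusted p = 0.993 for each), and with the replicate block limma's adjusted p lay between 0.159 and 0.281. The probe sets of a gene disagreed in sign for Map3k20, Glt8d1, Megf9 and Map4. Of the 24 genes 19 had several probe sets, and for 10 of them the difference shrank by over 1.5 times over the mean of all probe sets. These were Mycl, Map3k20 (0.16 log2), Gas2 (0.34), Tspan2 (0.50), Adgrf5 (0.59), Megf9 (-0.32), Map4 (-0.35), Glt8d1 (-0.48), Nfic (-0.52) and Tpcn1 (-0.53).

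**Figure D2:**
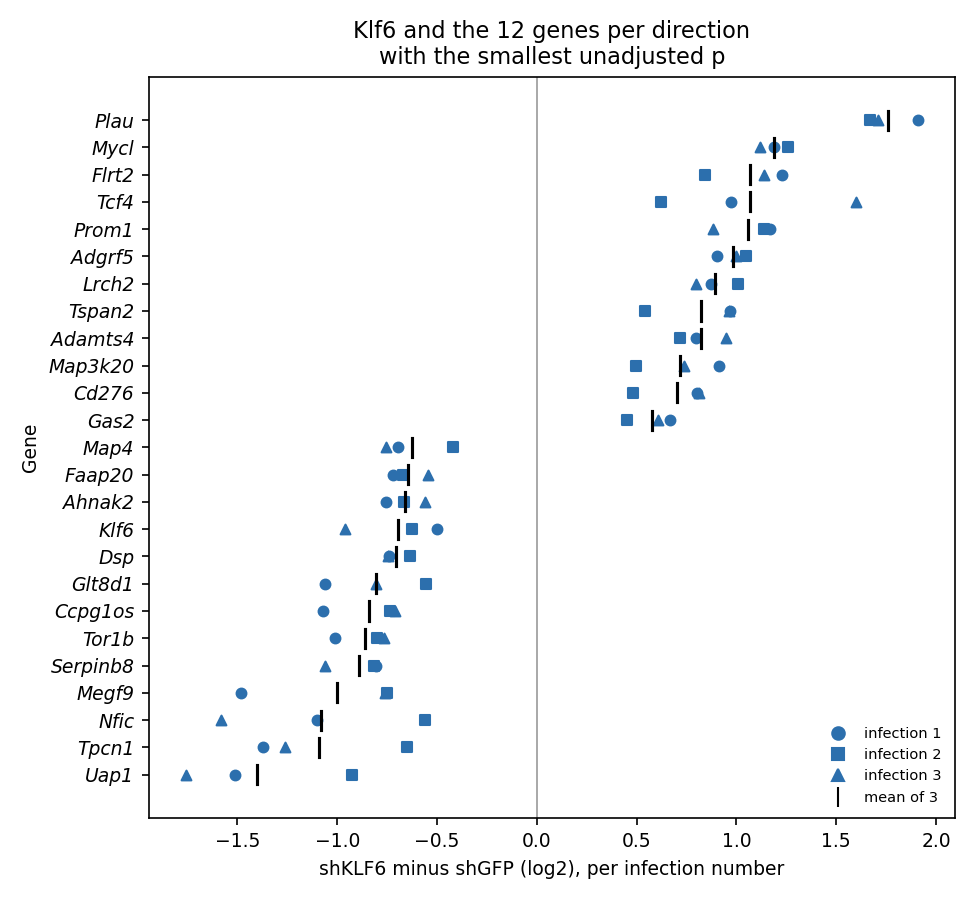
Difference shKLF6 minus shGFP (log2, horizontal axis) within each infection number (markers) and its mean (black bars) for Klf6 and the 24 genes with the smallest unadjusted p. For each gene the 3 markers lie on the same side of 0, from Plau at a mean of 1.76 to Uap1 at -1.40, and none of the genes passed the adjusted test.

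Within the fixed gene lists, some single genes passed when adjusted over their list alone, among them the protease gene Plau. The matrix genes Lamb1 and Fbln1 did so only with the replicate block. Adjusted over the list alone, limma without the block called 3 genes in 4 lists: Plau among proteases and invasion (adjusted p = 0.0145) and among reported KLF6 targets (adjusted p = 0.0124), Dsp in epithelial adhesion (adjusted p = 0.0237) and Prom1 among fetal liver and progenitor genes (adjusted p = 0.038). With the replicate block the same adjustment in limma called 25 of the 938 genes in the lists, 13 higher and 12 lower in 13 lists. These counts are not adjusted across the lists, and over all genes 0 were called. When the arrays were split in the other ways that part all 3 pairs, the blocked count was 6, 1 and 1 in place of 25.

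In the TGF-beta response list 6 of 26 genes passed when adjusted over the list alone with the block. The ligand gene Tgfb1 was lower (-0.49 log2; limma adjusted p = 0.0307), as were the signal transducer Smad3 (-0.45), the inhibitory Smad6 (-0.68) and Id2 (-1.21), whereas the matrix protein gene Tgfbi (2.08) and the activin antagonist follistatin, Fst (1.30), were higher. Tgfbi was 2.94, 2.67 and 0.64 log2 higher in infections 1, 2 and 3. Of 27 protease genes 3 passed in this way, Plau, Adamts1 (0.92) and the stromelysin gene Mmp3 (1.03), and of 31 matrix genes 2 did, the laminin chain Lamb1 (1.37) and the proteoglycan Vcan (0.67). The mesenchymal list had 4 of 29, with Tgfbi, Mmp3 and the collagen gene Col1a1 (0.71) higher and Twist2 (-0.90) lower. Fbln1, which encodes a matrix glycoprotein, passed in the stellate cell and fibroblast list, at 6.07 ± 0.85 in shGFP and 8.02 ± 0.54 in shKLF6 cells (SD, n = 3 each), 3.85-fold higher.

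The remaining genes called in this way stood in lists of several functions. In the KLF and SP family 2 of 19 genes passed, Klf6 itself and Klf4 (-0.61 log2; limma adjusted p = 0.0241 for both), and Klf13 (-0.23) had the smallest p without the block. The retinoblastoma gene Rb1 was lower (-0.73) and was the only 1 of 21 cyclin, CDK and inhibitor genes to pass. In epithelial adhesion 3 of 25 genes passed, with Dsp and the tight junction gene Cldn2 (-0.60) lower and Cldn1 (1.33) higher, although its shGFP level of 3.77 lay within the arrays' lower quartiles of 3.73 to 3.79 and is not shown to be above background. Cpt1a, which controls fatty acid entry into mitochondria, was lower (-1.05), the chaperone genes Hspb8 (-0.92) and Hsph1 (0.57) moved in opposite directions, and the carbonic anhydrase gene Car12 (1.05, or 0.42 over the mean of its probe sets) was higher. Of 23 reported KLF6 targets 3 passed, with Plau and Col1a1 higher and Tgfb1 lower. The list sets no expected direction, so these calls do not show that the genes respond to KLF6 as reported. Over the mean of all their probe sets Tgfb1 stood at -0.19, Smad3 at -0.26, Rb1 at -0.46, Lamb1 at 0.80, Vcan at 0.23 and Cldn1 at 0.56 log2, each over 1.5 times smaller.

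As sets, genes of ribosome biogenesis rose while genes of oxidative phosphorylation and fatty acid synthesis fell, by small amounts, under the preset inter-gene correlation. With an estimated correlation 0 of the 43 lists passed in limma camera, and the unadjusted p was 0.269, 0.416 and 0.340 for these 3 in that order (lowest adjusted p = 0.989 over all lists). The estimated correlations were 0.370, 0.509 and 0.388, above the preset 0.01. With so few degrees of freedom this version could hardly have called a list, so neither version settles whether these sets moved. Of 28 MYC target genes of ribosome biogenesis 23 were higher in shKLF6 cells, with a median of 0.13 log2 (limma camera, adjusted p = 0.00710 at the preset correlation). Among them were Mybbp1a (0.48), Ppan (0.47), the dyskerin gene Dkc1 (0.43) and Nop16 (0.34), while Ldha stood at -0.19. Of 31 oxidative phosphorylation genes 28 were lower, with a median of -0.11 (limma camera, adjusted p = 0.0295 at the preset correlation), such as Ndufa4 (-0.54), Sdhc (-0.39), Ndufs8 (-0.27) and Ndufv1 (-0.20), against 0.18 for Uqcrc1. Of 22 fatty acid synthesis genes 15 were lower, with a median of -0.22 (limma camera, adjusted p = 0.0420 at the preset correlation), such as Agpat2 (-0.55), the desaturase gene Scd1 (-0.54), Gpam (-0.39) and Elovl1 (-0.37), against 0.20 for Thrsp. None of these members passed alone. Within infections 1, 2 and 3 the median was 0.02, 0.17 and 0.23 for ribosome biogenesis and -0.25, -0.04 and -0.14 for oxidative phosphorylation. For fatty acid synthesis it was -0.27, 0.02 and -0.39. The sign held in all 3 infections for 14 of 28 ribosome biogenesis, 17 of 31 oxidative phosphorylation and 9 of 22 fatty acid synthesis genes. The poly-A labelling controls also differed between the groups, by -0.54 log2 (exact permutation p = 0.2) and by -0.67, -0.87 and -0.10 within infections 1, 2 and 3. The 3' minus 5' difference of Gapdh was higher in shKLF6 in each infection, by 0.05, 0.03 and 0.04.

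With the replicate block limma's camera kept ribosome biogenesis (adjusted p = 0.00398) and oxidative phosphorylation (adjusted p = 0.0104), lost fatty acid synthesis (adjusted p = 0.0669), and called mitosis and G2/M lower (adjusted p = 0.00398, against 0.454 without the block). With the block and an estimated correlation the unadjusted p in limma was 0.111 for ribosome biogenesis, 0.458 for oxidative phosphorylation and 0.475 for mitosis. Of 35 mitosis genes 30 were lower, with a median of -0.19 but medians of -0.56, 0.17 and -0.12 in infections 1, 2 and 3, and examples were Mki67 (-0.79), Kif23 (-0.73), Cenpf (-0.64), Cdca8 (-0.26) and Anln (0.03). The blocked splits that part all 3 pairs gave 7, 16 and 10 lists in place of 3.

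The list calls changed when single arrays were left out and when the labelling controls were a covariate. The fits without 1 array did not use the block. Leaving out an array also unbalances the infections, so differences between infections enter these fits. Dependence on a single array cannot be told apart from this imbalance. Leaving out 1 array moved the median of ribosome biogenesis between 0.03 (without shKLF6 3, 12 of 28 genes lower) and 0.26 (without shKLF6 1), and without shGFP 1 and 2 it was -0.02, with 15 of 28 lower. That of oxidative phosphorylation lay between -0.03 (without shGFP 3) and -0.24 (without shGFP 2), and that of fatty acid synthesis between -0.11 (without shGFP 1) and -0.35 (without shGFP 2). Camera's adjusted p in limma for ribosome biogenesis was 0.161 without shGFP 1, 0.577 without shKLF6 3 and 0.294 without shGFP 1 and 2. In limma this adjusted p was 0.826 with the poly-A level as a covariate and 1.93e-04 with this covariate and the block, where the unadjusted p with an estimated correlation was 0.905 and 0.133. Leaving out any other single array kept the call of ribosome biogenesis, from an adjusted p of 0.0130 without shKLF6 2 to 5.00e-08 without shKLF6 1 in limma, with an unadjusted p of 0.131 or more at an estimated correlation. For oxidative phosphorylation limma gave an adjusted p of 0.161 without shGFP 1, 0.589 without shGFP 3, 0.198 without shKLF6 1 and 0.297 without shKLF6 2, but 9.64e-06 without shGFP 2 and 0.00129 without shKLF6 3 (unadjusted p = 0.208 and 0.361 with an estimated correlation). In limma its adjusted p was 1.49e-05 without shGFP 1 and 2, 4.08e-05 with the covariate and 0.0533 with the covariate and the block, and with an estimated correlation the unadjusted p of these fits was 0.267, 0.235 and 0.681. For fatty acid synthesis limma gave an adjusted p of 0.546 without shGFP 1, 0.198 without shGFP 3, 0.210 without shKLF6 2 and 0.236 without shKLF6 3, but 4.52e-05 without shGFP 2 and 3.36e-04 without shKLF6 1 (unadjusted p = 0.131 and 0.190 with an estimated correlation). Its adjusted p in limma was 0.00942 without shGFP 1 and 2, 0.1 with the covariate and 6.88e-06 with the covariate and the block, and with an estimated correlation the unadjusted p of these fits was 0.307, 0.525 and 0.194. Mitosis without the block passed as lower in limma after leaving out shGFP 2 (adjusted p = 2.56e-05), shKLF6 3 (adjusted p = 8.62e-05) or both shGFP 1 and 2 (adjusted p = 3.37e-09), and with the covariate (adjusted p = 3.22e-09). With an estimated correlation the unadjusted p in limma was 0.407, 0.411, 0.319 and 0.278 for these 4 fits. In the last 2 its median was -1.06 and -1.08 log2 in place of -0.19, with 35 of 35 genes lower. Both fits were unpaired and rest wholly or mainly on shGFP 3, where the list's mean level was highest, at 10.3. They therefore mix the infection with the knockdown. With the covariate and the block the median was -0.20, with 31 of 35 genes lower (limma camera, adjusted p = 0.0224). There the unadjusted p in limma camera with an estimated correlation was 0.651. Its direction in limma camera turned to higher without shGFP 3 (adjusted p = 0.198) and without shKLF6 2 (adjusted p = 0.661).

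**Figure D3:**
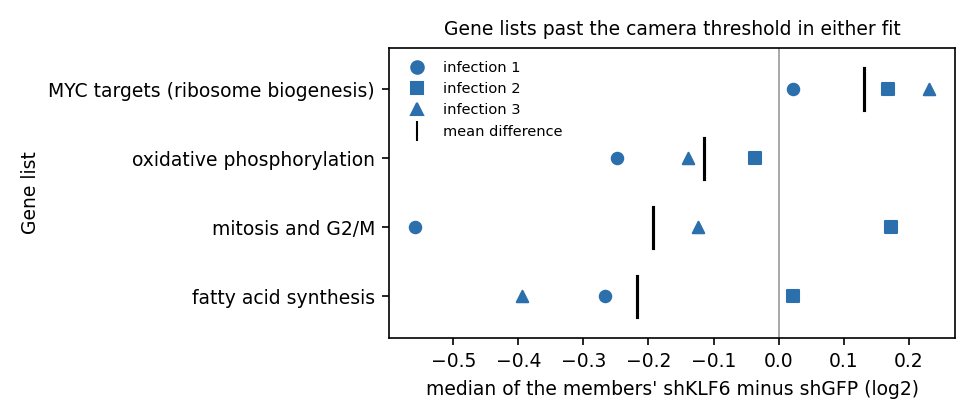
Median over the members of the shKLF6 minus shGFP difference (log2, horizontal axis) for the 4 lists past the camera threshold with or without the block, within each infection (markers) and for the mean difference (black bars). Ribosome biogenesis lies above 0 and oxidative phosphorylation below 0 in 3 of 3 infections. They lie close to 0 in infection 1 (0.02) and infection 2 (-0.04), respectively. Mitosis and fatty acid synthesis lie above 0 in infection 2, at 0.17 and 0.02.

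The other lists did not pass, at limma camera adjusted p between 0.167 and 0.979 for the 40 lists not called without the block. Among growth lists limma camera gave an adjusted p of 0.948 for DNA replication (Cdt1, a licensing factor, at 0.67 log2), 0.592 for cyclins, CDKs and inhibitors, 0.728 for p53 targets (Phlda3, -0.59) and 0.948 for apoptosis regulators (Bik, 0.19). For the KLF and SP family it gave an adjusted p of 0.592, and for reported KLF6 targets 0.735, both in limma. Of the signalling lists, limma camera gave an adjusted p of 0.948 for TGF-beta response, 0.948 for YAP/TEAD targets (Tgfb2, 0.58), 0.948 for NOTCH (Notch3, 0.38), 0.682 for WNT (the cyclin gene Ccnd1, -0.38), 0.591 for IGF, EGF and HGF signalling (Tgfa, -0.76, with 1 of 3 probe sets in this direction) and 0.592 for immediate early genes (Junb, -0.46). Inflammation had an adjusted p of 0.948 (the chemokine gene Cxcl1, -0.71) and interferon response 0.948 (Psmb8, 0.57) in limma camera.

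Of the adhesion and matrix lists, limma camera gave an adjusted p of 0.592 for epithelial adhesion, 0.684 for the mesenchymal list, 0.454 for extracellular matrix, 0.454 for integrins (Itgb6, -0.90) and 0.454 for proteases. Among stress lists the adjusted p in limma camera was 0.591 for the unfolded protein response (Pdia4, 0.44), 0.948 for the amino acid response (Slc7a5, -0.46), 0.684 for oxidative stress (heme oxygenase Hmox1, 0.37), 0.979 for heat shock and 0.735 for hypoxia. In metabolism limma camera gave an adjusted p of 0.303 for sterol synthesis (Dhcr7, -0.57), 0.591 for fatty acid oxidation (Cpt2, -0.57), 0.948 for glycolysis (Pklr, -0.17) and 0.591 for cytochrome P450 genes (Gstm2, 0.99). The proteasome (Psma5, -0.21) had an adjusted p of 0.735, and autophagy and lysosome (the kinase gene Ulk1, 0.44) of 0.948, in limma camera.

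Markers of other cell types did not pass in limma camera either. The stellate cell and fibroblast list was higher by a median of 0.17 log2 (adjusted p = 0.167, limma), and its mean level was 6.18 in shKLF6 3 against 5.29 to 5.44 on the other arrays. In limma camera the adjusted p was 0.167 for fetal liver and progenitor genes, 0.454 for hepatocyte genes (Apoh, 0.46, against a list median of -0.10), 0.948 for cholangiocyte (Krt23, 1.03), 0.682 for endothelial (Vwf, 0.23), 0.735 for macrophage (Laptm5, 0.33) and 0.454 for lymphocyte genes (Cd79b, 0.43). With fry the lymphocyte list was the only list past the threshold in limma (adjusted p = 0.0398), and with the replicate block 0 lists passed limma's fry (adjusted p = 0.339 for this list). The lymphocyte list had mean levels of 4.44 to 4.51 on all arrays, below each array's median of at least 5.18. Ribosomal proteins (Rps6, -0.36) and the cells' own small RNA machinery (Prkra, 0.38) each had an adjusted p of 0.948 in limma camera. None of the genes named here as leading members passed over all genes. Of these Cd79b, Notch3 and Vwf had shGFP levels at or below the arrays' lower quartiles. The probe sets disagreed in sign for Laptm5 (2 of 5 in the direction given), Pklr (1 of 3), Rps6 (1 of 2), Car12, Klf13 and Bik (2 of 3 each). Over the mean of all probe sets the differences of these 6 genes and of Tgfa, Cenpf, Gpam, Nop16, Notch3, Pdia4, Prkra, Sdhc and Thrsp shrank by over 1.5 times, and that of Pklr turned to 0.05 log2. Median, mean and camera direction differed in sign for epithelial adhesion, reported KLF6 targets, endothelial, interferon, apoptosis, ribosomal protein, small RNA, amino acid response, cholangiocyte and NOTCH lists.

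Mean levels of the mitosis and immediate early lists also varied with the infection number. The mean level of the mitosis list was 9.42, 8.43 and 10.3 in shGFP cells and 8.83, 8.55 and 10.14 in shKLF6 cells of infections 1, 2 and 3. Between infections its lowest p in limma camera with an estimated correlation was 0.125 (adjusted p = 0.716). Immediate early genes, which are induced soon after stimulation, were highest in infection 2, at 9.67 in shGFP and 9.28 in shKLF6 cells. The poly-A RNA controls, bacterial transcripts added before labelling, stood at 9.89 and 9.88 in shGFP 1 and 2 and between 9.02 and 9.23 in the shKLF6 arrays, with 9.13 in shGFP 3. The 3' minus 5' difference of Actb, a measure of RNA integrity, was 0.69 ± 0.26 in shGFP and 0.56 ± 0.09 in shKLF6 (SD, n = 3 each; exact permutation p = 0.7), and that of Gapdh was 0.06 ± 0.07 and 0.10 ± 0.07 (exact permutation p = 0.6). Within the infections Gapdh differed by 0.04 ± 0.01 on average, with the same sign in 3 of 3 (exact sign-flip permutation p = 0.25, the smallest possible), and Actb by 0.01, -0.41 and 0.02.

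**Figure D4:**
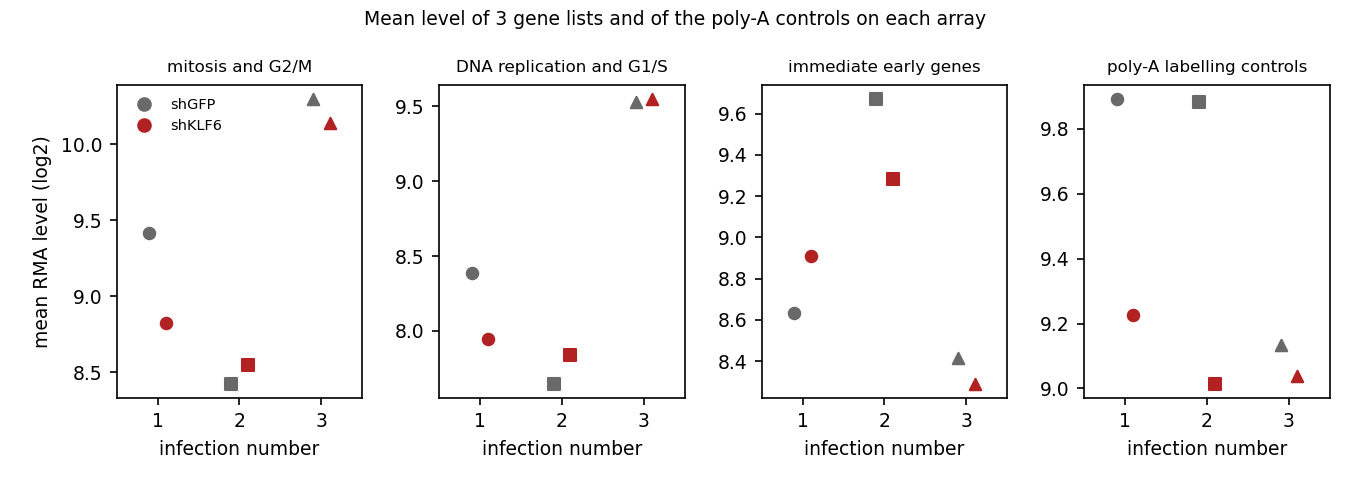
Mean RMA level (log2, vertical axes with different ranges) of 3 gene lists and of the poly-A labelling controls on each array, by infection number, with shGFP in grey and shKLF6 in red. In both groups mitosis and DNA replication were highest in infection 3, with mitosis at 10.3 and 10.14, and immediate early genes in infection 2. In infection 1 mitosis differed between the groups, at 9.42 in shGFP and 8.83 in shKLF6. The poly-A controls set shGFP 1 and 2 apart at 9.89 and 9.88.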

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

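The poly-A covariate, leaving out shGFP 1 and 2, and the block with an estimated inter-gene correlation or with the poly-A covariate were chosen only after the results were seen. Limma called 0 genes under each planned and added setting except without shKLF6 3, so that leaving out 1 array gave 0 to 2 genes; the 2 were Slc43a3 and Heph (adjusted p = 0.0427 in limma), named after their values were seen, at 0.21 and 0.06 log2 in infection 3 and above 2 log2 in the others. The count at an unadjusted p under 0.05 was 864, and was 3046 with array weights, 1902 with the replicate block, 396 over the 9097 genes with a mean level above the median, and 449 to 1868 without 1 array. Klf6 stayed lower under all 18 settings, from -0.02 with array weights to -1.13 without shKLF6 2; its unadjusted limma p fell under 0.05 only with the replicate block, to 0.00254 at the same -0.70, since the spread between infections left the residual, and with the block and the poly-A covariate, to 0.0124 at -0.98, whereas with the poly-A covariate alone it was 0.818 at -0.18. Without 1 array the Klf6 difference was -0.29 to -1.13. The count of lists was 3, and was 1 after quantile normalization, in the genes above the median level and without _x_at and _s_at probe sets, 7 with array weights, 0 to 13 without 1 array (0 without shGFP 1, 13 without shGFP 2, 6 without shKLF6 3), 1 with fry, 0 with an estimated correlation with or without the block, 10 with the poly-A covariate, 15 with it and the block and 15 without shGFP 1 and 2; the cause was not tested. The replicate block changed no other printed call than those of Klf6, mitosis, fatty acid synthesis, the lymphocyte list in fry and the genes adjusted over a list alone. Of 64 named genes 60 kept their sign in every setting, and the exceptions were Pklr, Krt23, Psma5 and Vwf. Of simulated 2-fold changes 28% were recovered without the block and 50% with it, so smaller changes lay mostly below detection. Larger changes planted in the same run eased the adjusted threshold, so these shares may be too high for these arrays.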

Other observations

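The infection comparison, the tests of the labelling controls, of 3'/5' differences and of proliferation were chosen only after the result was seen, as were the corrections with the poly-A covariate and without shGFP 1 and 2, the blocked counts over other splits and the comparison of infection 3 and Klf6 values with the spread between arrays, pairs or splits; the other tests of splits, infection 3 and Klf6 were not. With the hairpin held in the fit and 2 arrays per infection, limma found 1479 genes different between infections 3 and 2 (828 higher and 651 lower in infection 3), 302 genes by the F-test over all infections, and 0 genes between infections 2 and 1 (2326 at an unadjusted p under 0.05) or between 3 and 1 (3716). Of 34 DNA replication genes 22, and of 35 mitosis genes 21, were among the 302. As lists neither passed with an estimated correlation, where the smallest p over the contrasts in limma camera was 0.109 and 0.125. With 2 arrays per infection that test could hardly have called a list. Cdc6, which loads the replicative helicase, was 3.47 log2 higher in infection 3 than in infection 2, cyclin E2 (Ccne2) 3.44, the mitotic transcription factor Foxm1 2.35 and the helicase subunit Mcm4 1.90 (limma F-test, adjusted p = 0.0458 for each).

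Some stress and early response genes ran the other way. Atf3, a stress-induced factor and reported KLF6 target, differed by -2.98 log2 between infections 3 and 2, and the oncostatin M receptor gene Osmr by -2.79 (limma F-test, adjusted p = 0.0458 for both). The median was -0.98 log2 over immediate early genes, -0.84 over the amino acid response and -0.44 over the KLF and SP family, of which 4 of 29, 3 of 28 and 4 of 19 genes were among the 302, whereas it was 0.40 over oxidative stress and 0.42 over heat shock genes. In limma camera 14 lists passed for this contrast and 0 did with an estimated correlation (lowest adjusted p = 0.716). All named genes of this contrast were chosen after their values were seen.

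The first pattern is the likeness of arrays with the same infection number, which was weakest for infection 1 (correlation of deviations 0.28). A labelling batch marked by the poly-A controls is argued against, since 2 of the 3 pairs differed in these controls by over 0.5 log2, up to 0.867. RNA degradation stays open, because the largest difference within a number was 1.36 times the range between numbers for Actb but 0.359 times for Gapdh. A difference in the proliferation state of the cultures, which may be biological, also stays open. The mitosis median moved by up to 1.61 log2, and 21 of 35 mitosis genes were among the 302 of the F-test. In limma camera with an estimated correlation its smallest p was 0.125. With 2 arrays per infection that test could hardly give a small p, so it speaks neither for nor against such a difference. The labels give no density or day of harvest, so culture state and preparation cannot be told apart here.

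The second pattern is the higher poly-A controls of shGFP 1 and 2, by 0.78 log2 over the other 4 arrays. The hybridization controls moved the same way, 0.251 times as much. Quantile normalization removes a shift in the brightness of a whole array, so this comparison could not have shown brighter arrays. A separate labelling batch or less sample RNA per reaction cannot be told apart from other sources, since 0 labels set these arrays apart. In infection 3, where both arrays had like controls (9.13 and 9.04), the list medians were 0.23 for ribosome biogenesis, -0.14 for oxidative phosphorylation and -0.39 for fatty acid synthesis. By the bound set beforehand these values would have excluded the labelling difference as the cause, but that bound used only the spread between members. Infection 3 is a single pair of arrays, so its spread between pairs is unknown. Against the SD of the 3 paired medians the values were 2.15, 1.32 and 1.85 times as large. A bar of 4.30 was set for this after the values were seen. The SD includes the value it is compared with, so this bar decides nothing either way. With the poly-A covariate the medians were -0.06, -0.27 and -0.24, and with it and the block 0.23, -0.17 and -0.43. For ribosome biogenesis the unpaired covariate and leaving out shGFP 1 and 2 (-0.02) removed the shift, and only the paired covariate kept it. No such correction shrank the oxidative phosphorylation or fatty acid synthesis shift. However, the unpaired corrections rest wholly or mainly on shGFP 3 as the control, so differences between infections enter them. Infection 3 stood above infections 2 and 1 by a median of 0.30 and 0.16 log2 in oxidative phosphorylation. In fatty acid synthesis these medians were 0.22 and -0.20, and in ribosome biogenesis 0.15 and 0.30. A control taken from infection 3 alone would therefore by itself lower the ribosome biogenesis shift. The fit with covariate and block estimated nearly as many terms as there were arrays. These corrections therefore cannot decide whether labelling is the whole cause. In limma camera with an estimated correlation p was 0.133 or more in the fits with the covariate. Across infections 1, 2 and 3 the medians of none of these lists followed the size of the poly-A difference (-0.67, -0.87 and -0.10). With 3 pairs this cannot settle the question. The labelling difference may still contribute to each shift.

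The third pattern is that Klf6 varied more between infections than with the knockdown. If genes that follow Klf6 between infections also followed the knockdown, the infection 3 minus 2 differences would correlate positively across genes with the shKLF6 minus shGFP differences. Over the other 18193 genes Pearson's r was -0.26 and Spearman's rho -0.20, across genes, which are not independent replicates. The bound set beforehand (r of 0.1 or less) would have excluded the hypothesis, but the other splits that part all pairs gave r up to 0.566 in size, so the value lies within what regrouping gives. It may be that other differences between infections hide such genes, which was not tested.

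For the real split limma called 0 genes and camera 3 lists, and the highest of the other splits of the 6 arrays gave 1476 genes and 15 lists. With 0 genes in the real split all 10 of the 10 splits must give as many, which tests nothing; 9 of 10 gave as many lists, and with 10 splits the share cannot fall under 0.05. The split with 1476 genes set shGFP 1, shGFP 3 and shKLF6 3 against the rest. It parts 1 pair, that of infection 1, so it points to a structure by infection only in part. Among the splits that part all 3 pairs, the blocked count at an unadjusted p under 0.05 was 1902 for the real one against 885, 386 and 317, with 0 genes past the adjusted threshold in each.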
